A study of Mus musculus with 6 samples.

How the data were processed

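RNA was extracted from frozen mouse liver with the RNeasy Plus Mini kit and its quality was read on a Bioanalyzer, per the labels' protocols, and libraries were made with standard Illumina methods. The 6 libraries fall into 2 groups of 3 by the genotype in the labels, wild type (WT) and Alb-CreERT2 with floxed Pten and Traf3 (KO). The values are FPKM (fragments mapped to a gene, scaled by transcript length and by the mapped fragments of the library), deposited by the authors as 1 list of gene symbols and values per library, with no read counts. TopHat2 2.1.1, Cufflinks 2.2.1 and the mouse genome build mm10 are named in the submitters' processing notes. Their roles, the gene annotation, the handling of reads shared between genes, the strand setting and the sequencing depth are not given in the sources used here.

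Values start at 0.1 or 0.101 FPKM in each library, so genes under 0.1 appear to have been removed before deposit, which is read from the values alone. Libraries listed 13077 (WT-1), 13311 (WT-2), 13907 (WT-3), 12644 (KO-1), 12792 (KO-2) and 12890 (KO-3) genes. The lists were nested in the order WT-3, WT-2, WT-1, KO-3, KO-2, KO-1, each holding all genes of the next, so absence from a list cannot be read as a low value in that library alone. Of 13907 genes, 12644 were listed in all libraries and 1263 in some only, and the latter were left out of the tests. Total FPKM was 663812, 648023 and 619539 in WT-1 to WT-3 and 675254, 546953 and 570395 in KO-1 to KO-3, and the median value lay between 5.3 and 5.53. Since fragments are whole, ratios of low values (under 1 FPKM) between libraries gather at the ratio of what 1 fragment is worth. This gave relative depths of 0.926, 0.907 and 1 for WT-1 to WT-3 and 0.924, 1 and 0.91 for KO-1 to KO-3, with absolute depth unknown, so no counting interval is given. No pair of libraries held the same values (0.00791% to 1.06% of values equal, the highest for WT-3 and KO-2, whose fragments were worth the same).

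Genes listed in all libraries with a mean of at least 0.5 FPKM (11825 genes) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a variance trend, no scaling between libraries beyond FPKM and no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was called. The design, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Pten and Traf3 were also tested with an exact two-sided permutation test over all splits of the libraries. Gene lists with at least 3 tested members were tested with camera (preset correlation 0.01) and adjusted over the 34 lists so tested, with a correlation estimated per list and with fry as alternatives, and members were also adjusted over the list alone. The 37 lists cover liver cell types, hepatocyte functions, lipid and glucose metabolism, NF-kB and other signalling, stress, and checks of sex, blood and handling. They came from textbook knowledge and some genes stand in several lists.

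Genes named were Pten and Traf3, the 12 largest rises and 12 largest falls among called genes with no overlap between groups and a group mean of at least 5 FPKM (predicted genes and pseudogenes skipped), up to 2 called members each way per list or else the 2 most abundant members, and a fixed set of liver genes such as Alb, Fasn, Map3k14 and Spp1. This rule named 95 genes. Acacb, Me1, Plin2, Thrsp, Elovl6, Ldlr, Csf1r, Vsig4, Lyz2, Ehhadh, Pck1, Cdkn1a, Hspa5 and Creld2, and the genes named only in the closing observations, fall outside it and were chosen after their values were seen. Coordinates are those of GENCODE M21 on GRCm38, the same assembly as mm10, matched by symbol. Of the 13907 symbols 13393 matched, and 11387 of the 11825 tested genes matched 1 gene.

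The test was first run on simulated data with the spread of these libraries, 11825 genes, 200 of them changed, in 5 runs. It recovered 69.6% of log2 changes of 1 and 97% of log2 changes of 2, with 4.91% false calls. A simulated list of 15 genes shifted by 0.5 had an unadjusted camera p under 0.05 in 5 of 5 runs. Genes were drawn independently, and genes of low abundance were not among those changed. The runs therefore do not show how the list test behaves when members are correlated. The alternatives were 0.1 as the added constant, no filter or a mean of at least 2 FPKM, median-of-ratios scaling, quantile normalization, no variance trend, robust moderation, the replicate number as a block, missing genes set to 0, a change of at least 1 on the log2 scale required as well, and each library left out in turn. An alternative without the 10 most abundant genes was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.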

Results

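Liver RNA was sequenced in 3 libraries from wild-type C57BL/6 mice (WT-1 to WT-3) and 3 libraries from C57BL/6 mice carrying Alb-CreERT2 with both Pten alleles and both Traf3 alleles floxed (KO-1 to KO-3). Alb-CreERT2 is a Cre recombinase driven by the albumin promoter, which is active in hepatocytes, and it becomes active when tamoxifen is given. Pten is the lipid phosphatase that opposes PI3K signalling, and Traf3 is an adaptor that keeps the kinase NIK (Map3k14) at low levels. The comparison asks which transcripts differ between livers with both genes targeted in hepatocytes and wild-type livers. No group had only Pten or only Traf3 targeted, so the parts of the 2 genes could not be separated. The wild-type labels name no Cre and no floxed alleles, and no group carried Alb-CreERT2 without floxed alleles. Effects of Cre, of the floxed alleles themselves, or of any difference in tamoxifen or breeding could therefore not be separated from loss of the genes. The age and sex of the mice, their feeding, and the timing of tamoxifen were not given in the sources used here. Nothing in the labels states how the mice were related or that each library came from its own mouse, so p-values measure only the spread between these libraries.

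Each library was given as FPKM values for 12644 to 13907 genes, with no read counts. Absolute depth was therefore unknown, and the low values put the relative depth of the libraries between 0.907 and 1. The libraries listed nested sets of genes, with WT-3 the longest and KO-1 the shortest list, and no value lay under 0.1 FPKM. A gene absent from the WT-3 list is in no list, so transcripts present only in the knockout group could not be seen. Pearson correlations between libraries averaged 0.985 within groups (6 pairs, 0.981 to 0.991) and 0.976 between groups (9 pairs, 0.971 to 0.982). The first principal component held 42.4% of the variance and separated the groups, with scores of -13.4, -20.3 and -20.6 in the wild-type libraries and 19.9, 24.4 and 9.95 in the knockout libraries. The second held 24.3% and set WT-1 (17.1) and KO-1 (20.6) apart from the others (-18.4 to -2.46).

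**Figure D1:**
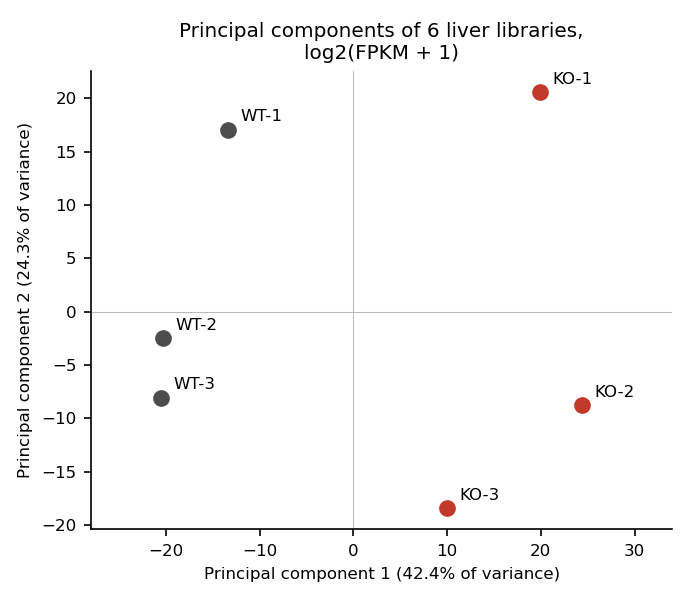
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1), with the share of variance of each component on its axis. The wild-type libraries lie between -20.6 and -13.4 on the first component and the knockout libraries between 9.95 and 24.4.

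Both targeted genes had lower values in every knockout library than in any wild-type library, and neither difference passed the test over all genes. Pten (chromosome 19, 32757497 to 32826160, GRCm38) was at 16.8, 19.2 and 19.1 FPKM in WT-1, WT-2 and WT-3 and at 11.7, 12.8 and 12.9 FPKM in KO-1, KO-2 and KO-3. The means were 18.4 ± 1.39 and 12.5 ± 0.664 FPKM (SD, n = 3 each), a knockout to wild-type ratio of 0.679. Traf3 (chromosome 12, 111166370 to 111267153) was at 1.64, 1.61 and 1.4 FPKM in the wild-type libraries and at 0.879, 1.25 and 1.07 FPKM in the knockout libraries, with a ratio of 0.688. The log2 differences were -0.52 (SE 0.115, limma adjusted p = 0.069) for Pten and -0.31 (SE 0.129, adjusted p = 0.297) for Traf3. The exact two-sided permutation test gave p = 0.1 for each, which is the smallest p that 3 against 3 allows. FPKM is a value per gene, so it does not separate transcripts with and without the floxed exons, and liver holds other cells in which Alb-CreERT2 is not active. With 0.1 in place of 1 added before the logarithm, the log2 difference of Traf3 was -0.51 (adjusted p = 0.306, range over its alternatives 0.257 to 0.596).

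Of 11825 genes tested with limma, 164 passed an adjusted p of 0.05, of which 99 were higher and 65 lower in the knockout livers, and 1858 had an unadjusted p under 0.05. In all 164 the 3 knockout values lay outside the range of the 3 wild-type values. This held for 2588 of the tested genes (21.9%), against 10% by chance. The count of 164 rested in part on single libraries, being 118 without WT-1, 19 without WT-2, 44 without WT-3, 85 without KO-1, 75 without KO-2 and 217 without KO-3. Each gene below is given as mean ± SD of FPKM over n = 3 libraries per group, and log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Counts of list members with higher or lower means go by the mean on that log2 scale, which can differ in sign from the mean of FPKM. Counts of members at an unadjusted p under 0.05 are to be read against the 1858 of all 11825 tested genes. Counts adjusted over a list alone are not corrected for the number of lists.

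Several of the 12 largest rises were in genes of fat storage, transport and synthesis. G0s2 (chromosome 1, 193272161 to 193273217), an inhibitor of the lipase ATGL, rose from 10.4 ± 5.35 to 169 ± 20.3 FPKM (16.2-fold, log2 4.01, adjusted p = 0.00373). Cd36 (chromosome 5, 17781690 to 17888801), a fatty acid transporter, rose from 5.36 ± 2.1 to 34.3 ± 14.5 FPKM (log2 2.44, adjusted p = 0.015). Scd1 (chromosome 19, 44394455 to 44407879), the desaturase that makes monounsaturated fatty acids, rose from 976 ± 339.9 to 4480.1 ± 1379.7 FPKM (4.59-fold, adjusted p = 0.0196). Pnpla3, a lipid droplet protein, rose from 1.19 ± 0.298 to 8.61 ± 4.81 FPKM (adjusted p = 0.0354), and Acot3, a peroxisomal acyl-CoA thioesterase, from 9.85 ± 9.21 to 83.7 ± 12.2 FPKM (adjusted p = 0.0203). Cyp2f2 (chromosome 7, 27119909 to 27133660), a cytochrome P450 of periportal hepatocytes, rose from 96.5 ± 21.4 to 605 ± 149.8 FPKM (6.27-fold, adjusted p = 0.00409). Inhbe, the activin E subunit, rose from 10.8 ± 1.81 to 58.5 ± 14.6 FPKM (adjusted p = 0.00409), and the bile acid transporter Slc10a2 from 2.07 ± 0.539 to 12.8 ± 1.99 FPKM (adjusted p = 0.00373). The others of the 12 largest rises were Mvd, an enzyme of cholesterol synthesis, the transporter Slc16a5, and Raet1d and Mup20, with adjusted p between 0.0189 and 0.0467. Mup20 was highest in KO-2, at 959 FPKM against 190 and 210 in KO-1 and KO-3. All 12 kept their direction with each library left out in turn, which was bound to hold because their groups do not overlap. Robust moderation lost the calls of Raet1d, Mup20 and Mvd and quantile normalization that of Mup20. Their calls numbered 10 without WT-1, 5 without WT-2, 5 without WT-3, 5 without KO-1, 6 without KO-2 and 12 without KO-3, and G0s2, Cyp2f2, Inhbe and Slc10a2 passed in every case.

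Among the 12 largest falls were binding proteins of insulin-like growth factors. Igfbp2 (chromosome 1, 72824503 to 72852474) fell from 179 ± 39.1 to 23.4 ± 15.9 FPKM (log2 -3.22, adjusted p = 0.0441), and Igfbp1 of the same family fell from 62.2 ± 21.3 to 16.6 ± 5.21 FPKM (adjusted p = 0.0334). Serpina1e (chromosome 12, 103946931 to 103958975), an alpha-1-antitrypsin, fell from 7269 ± 2334 to 1165 ± 389 FPKM (log2 -2.66, adjusted p = 0.0129). The aspartic protease Ctse fell from 5.17 ± 0.42 to 0.243 ± 0.068 FPKM (21.3-fold lower, adjusted p = 0.000426), the lowest adjusted p of all genes. Saa3, an acute phase apolipoprotein, fell from 62.5 ± 25.2 to 13.5 ± 3.85 FPKM (adjusted p = 0.0189). Lifr, the receptor of leukaemia inhibitory factor, fell from 386 ± 46.9 to 121 ± 62.8 FPKM (adjusted p = 0.0464), and Osgin1, a growth inhibitor induced by oxidative stress, from 122 ± 16.6 to 37.3 ± 11.5 FPKM (adjusted p = 0.015). Cyp3a16, Ptgds, Gbp2b, Nedd9 and Adamts7 completed the group, with adjusted p between 0.0189 and 0.0422. All 12 were lower with each library left out in turn, as the lack of overlap between their groups requires. Robust moderation lost the calls of Igfbp2, Cyp3a16 and Lifr and an added constant of 0.1 those of Igfbp2 and Gbp2b. The replicate number as a block lost those of Igfbp2, Ptgds, Igfbp1, Lifr and Gbp2b. With a library left out, the genes past the threshold numbered 7 without WT-1, 2 without WT-2, 5 without WT-3, 5 without KO-1, 6 without KO-2 and 10 without KO-3. Ctse was the gene of these 12 that passed in every case. Acot3, Raet1d, Mup20, Serpina1e and Cyp3a16 belong to families of near-identical genes, and how the submitters divided shared reads was not given, so their values are uncertain.

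**Figure D2:**
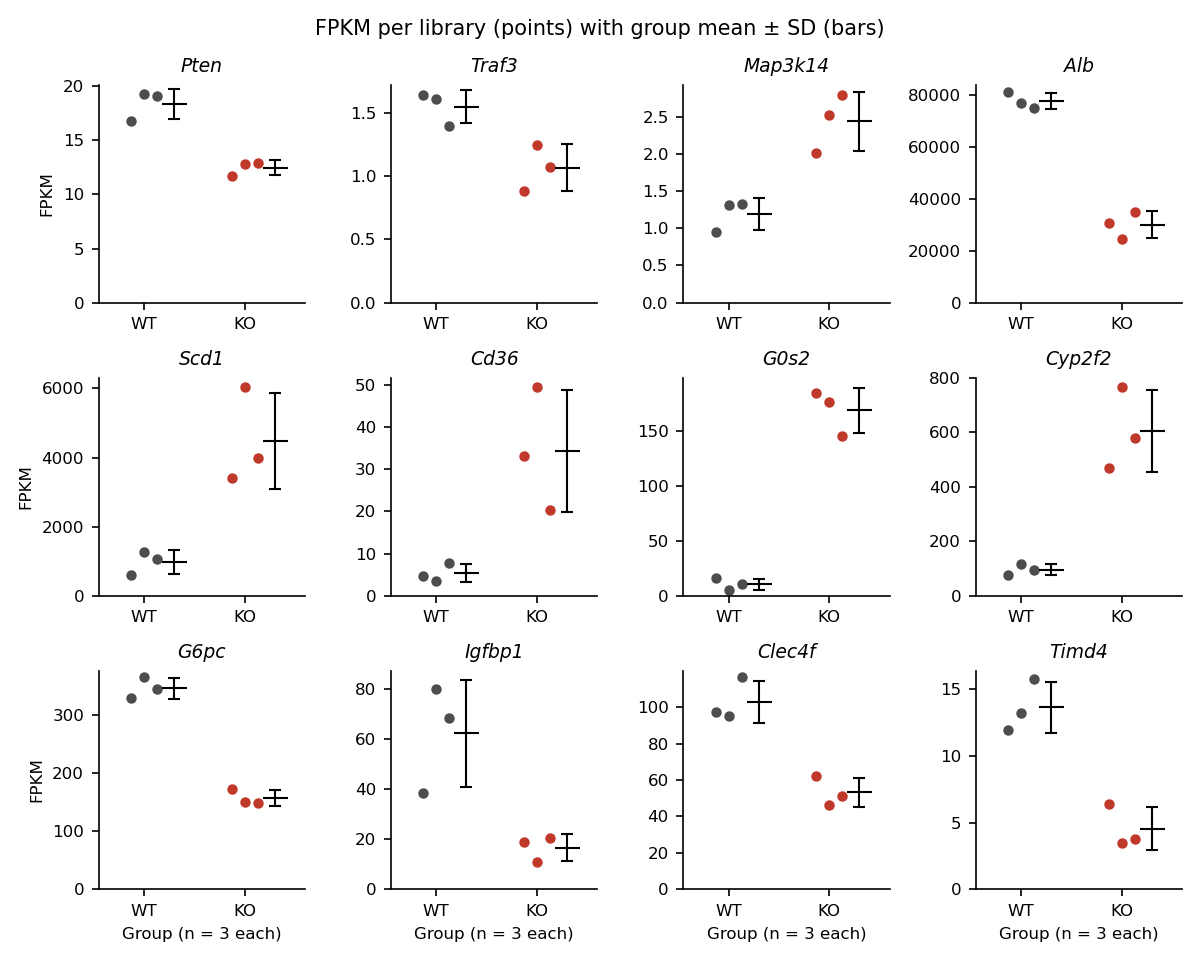
FPKM of 12 genes in each library (points), with the mean and SD of each group of 3 (bars). Pten and Traf3 are lower in every knockout library, Scd1, Cd36, G0s2 and Cyp2f2 are higher, and G6pc, Igfbp1, Clec4f and Timd4 are lower.

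Changes were then read by gene list. Of 37 lists fixed before the data were examined, 34 had at least 3 tested members. Camera with its preset correlation placed 19 past an adjusted p of 0.05, 10 higher and 9 lower in the knockout livers. With a correlation estimated per list 0 of the 34 passed camera and 5 had an unadjusted p under 0.05, against 4 past the adjusted threshold with fry, which asks whether the genes of a list move one way on balance. Those 4 were fatty acid synthesis, glycolysis and p53 targets upwards and macrophages downwards. The other 9 splits of the 6 libraries into 3 and 3 gave 8 to 18 lists with the same preset, so its p-values are read with the one from the estimated correlation beside each.

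Genes of fatty acid synthesis and lipid storage were higher as a group. Of 21 members tested 8 rose, 0 fell and 13 did not pass, and 18 had a higher mean of log2(FPKM + 1) in the knockout livers. Adjusted over the list alone, 14 passed. Besides Scd1, Cd36 and Pnpla3, the elongase Elovl6 rose from 13.1 ± 3.19 to 47.4 ± 8.78 FPKM (adjusted p = 0.00952). Malic enzyme Me1, a source of NADPH, rose from 60.9 ± 10.2 to 179 ± 49.6 FPKM (adjusted p = 0.0189), the lipid droplet coat protein Plin2 from 112 ± 31 to 303 ± 78.6 FPKM (adjusted p = 0.0341), and Thrsp, a regulator of lipogenesis, from 393 ± 28.8 to 1056 ± 289.9 FPKM (adjusted p = 0.0209). Acacb, an acetyl-CoA carboxylase, rose from 6.05 ± 1.25 to 20.8 ± 9.3 FPKM (adjusted p = 0.0456). Fatty acid synthase, Fasn, was at 66.9 ± 19.6 and 132 ± 39.9 FPKM (adjusted p = 0.111). Srebf1, which encodes the lipogenic transcription factor SREBP-1, was at 109 ± 34 and 96.7 ± 28.8 FPKM (log2 -0.17, adjusted p = 0.83) and its sign turned without WT-2 (0.03) and without KO-3 (0.08). The list's median log2 change was 1.14 (camera adjusted p = 1.3e-10, adjusted p = 0.19 with an estimated correlation, fry adjusted p = 0.0347). The number that rose was 6 without WT-1, 1 without WT-2, 2 without WT-3, 5 without KO-1, 4 without KO-2 and 8 without KO-3, and 1 member fell without KO-3.

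All 18 tested genes of cholesterol synthesis and uptake had higher means in the knockout livers, and 3 rose. Mvd, the mevalonate diphosphate decarboxylase, rose from 3.94 ± 1.71 to 21.5 ± 10.1 FPKM (adjusted p = 0.0422), squalene epoxidase Sqle from 15 ± 4.32 to 39.9 ± 7.86 FPKM (adjusted p = 0.0305), and the LDL receptor Ldlr from 38.2 ± 1.14 to 58.9 ± 3.79 FPKM (adjusted p = 0.0447). Adjusted over the list alone, 14 rose. The median log2 change was 0.65 (camera adjusted p = 3.38e-10, adjusted p = 0.19 with an estimated correlation, fry adjusted p = 0.0525). Without WT-2, WT-3, KO-1 or KO-2 the number that rose was 0, and it was 3 without WT-1 and 4 without KO-3. In the same livers, 19 of 20 genes of fatty acid oxidation and PPAR alpha targets had higher means, with Ehhadh, an enzyme of peroxisomal oxidation, as the exception at 542 ± 223 and 278 ± 104 FPKM. The peroxisomal thiolase Acaa1b rose from 319 ± 62.7 to 835 ± 174 FPKM (adjusted p = 0.0215) and Pdk4, the kinase that inhibits pyruvate dehydrogenase, from 1.15 ± 0.257 to 3.34 ± 0.0849 FPKM (adjusted p = 0.0137), and 18 did not pass. Adjusted over the list alone, 13 rose and 1 fell. The median was 0.48 (camera adjusted p = 1.21e-09, adjusted p = 0.419 with an estimated correlation, fry adjusted p = 0.0579). The count of 2 was 6 without WT-1, 0 without WT-2, 1 without WT-3, 2 without KO-1, 3 without KO-2 and 3 without KO-3, and it reached 7 when the 10 most abundant genes were left out.

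By camera, genes of gluconeogenesis and FoxO targets were lower and those of glycolysis higher as lists. G6pc (chromosome 11, 101367561 to 101377903), the glucose-6-phosphatase that releases glucose, fell from 346 ± 18.1 to 157 ± 14.1 FPKM (log2 -1.14, adjusted p = 0.0105). With Igfbp1, a FoxO target, it made 2 falls among 16 genes of gluconeogenesis and FoxO targets. Of the 16, 14 had a lower mean of log2(FPKM + 1), and 2 also fell adjusted over the list alone. Pck1, which makes phosphoenolpyruvate in gluconeogenesis, was at 1810.2 ± 80.9 and 1312 ± 652 FPKM (adjusted p = 0.426). The median log2 change was -0.24 (camera adjusted p = 0.00166, adjusted p = 0.466 with an estimated correlation). The number that fell was 2 without WT-1, 0 without WT-2, 1 without WT-3, 1 without KO-1, 1 without KO-2 and 2 without KO-3. Of 16 glycolysis and glucose uptake genes 0 passed limma over all genes, 2 were higher adjusted over the list alone and 5 were higher at unadjusted p under 0.05. Glucokinase, Gck, was at 43 ± 12.9 and 85 ± 15 FPKM (log2 0.99, adjusted p = 0.0765) and Gapdh at 575 ± 134 and 722 ± 102 FPKM. That list had a median of 0.24 (camera adjusted p = 0.00635, adjusted p = 0.223 with an estimated correlation, fry adjusted p = 0.0208).

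Markers of resident liver macrophages were lower in the knockout livers. Of 18 genes of Kupffer cells and macrophages 5 fell, 0 rose and 13 did not pass, 15 had lower means and 14 had all knockout values below all wild-type values. Timd4, a phosphatidylserine receptor of resident macrophages, fell from 13.6 ± 1.92 to 4.54 ± 1.61 FPKM (adjusted p = 0.019). Clec4f, a lectin of Kupffer cells, fell from 103 ± 11.7 to 53.2 ± 7.99 FPKM (adjusted p = 0.0282). The colony stimulating factor receptor Csf1r fell from 33.8 ± 7.01 to 17.2 ± 0.249 FPKM (adjusted p = 0.0318), the complement receptor Vsig4 from 51.7 ± 4.62 to 29.4 ± 4.75 FPKM (adjusted p = 0.0424), and lysozyme Lyz2 from 102 ± 11.6 to 59 ± 6.56 FPKM (adjusted p = 0.0433). Adgre1, which encodes F4/80, was at 9.86 ± 4.07 and 4.98 ± 1.03 FPKM (adjusted p = 0.168). Adjusted over the list alone, 13 fell. The median log2 change was -0.75 (camera adjusted p = 3.38e-10, adjusted p = 0.19 with an estimated correlation, fry adjusted p = 0.034). The number that fell was 2 without WT-1, 0 without WT-2, 0 without WT-3, 3 without KO-1, 0 without KO-2 and 2 without KO-3.

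Lists of neutrophil, T and NK cell and MHC class II genes were also lower by camera. Of these and of the B and plasma cell and red blood cell lists, neither of which passed camera, 0 members passed limma's threshold over all genes. Neutrophil genes (9 tested, 5 lower adjusted over the list alone and 6 lower at unadjusted p under 0.05) had a median of -1.03 (camera adjusted p = 4.12e-05, adjusted p = 0.49 with an estimated correlation), with S100a8 at 50.1 ± 26.9 and 22.5 ± 15.7 FPKM and S100a9 at 52.5 ± 25.8 and 19.7 ± 13 FPKM. T and NK cell genes (8 tested, 3 lower adjusted over the list alone and 3 lower at unadjusted p under 0.05) had a median of -0.34 (camera adjusted p = 0.00356, adjusted p = 0.49 with an estimated correlation), with the granule genes Gzma at 1.93 ± 1.01 and 0.539 ± 0.276 FPKM and Nkg7 at 1.75 ± 0.696 and 0.505 ± 0.304 FPKM. Genes of MHC class II presentation (8 tested, 0 adjusted over the list alone and 2 lower at unadjusted p under 0.05) had a median of -0.51 (camera adjusted p = 0.00356, range over alternatives 3.85e-05 to 0.563, adjusted p = 0.563 with an estimated correlation), with Cd74 at 157 ± 87.8 and 99.1 ± 14.6 FPKM and H2-Aa at 77 ± 43.6 and 49.4 ± 11.1 FPKM, and the list did not pass without WT-3 (0.143) or KO-3 (0.0546). B and plasma cell genes (6 tested, 0 adjusted over the list alone and 1 lower at unadjusted p under 0.05) had a median of -0.13 (camera adjusted p = 0.343, range over alternatives 0.0742 to 0.995) and turned upwards without KO-3 (0.995). Red blood cell genes (4 tested, 1 higher adjusted over the list alone and 1 higher at unadjusted p under 0.05) had a median of -0.86 (camera adjusted p = 0.587, range over alternatives 0.26 to 0.772), with Hba-a1 at 109 ± 87.3 and 50.5 ± 19.9 FPKM, and turned upwards without WT-1 (0.767) or KO-3 (0.755).

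Of the endothelial and the stellate cell markers 0 passed limma's threshold over all genes or adjusted over the list alone. All 16 liver endothelial genes had lower means (3 lower at unadjusted p under 0.05), with a median of -0.20 (camera adjusted p = 0.0104, range over alternatives 0.00014 to 0.70, adjusted p = 0.70 with an estimated correlation). Among them the sinusoidal lectin Clec4g was at 32.5 ± 5.5 and 24.3 ± 9.11 FPKM and Fcgr2b at 23 ± 2.63 and 21.1 ± 5.61 FPKM, and the list did not pass without WT-3 (0.379) or KO-1 (0.345). Stellate cell and fibroblast genes (22 tested, 4 higher at unadjusted p under 0.05) had a median of 0.20 (camera adjusted p = 0.0222, range over alternatives 7.03e-05 to 0.70, adjusted p = 0.70 with an estimated correlation), with Dcn at 107 ± 23.7 and 105 ± 3.8 FPKM and Sparc at 57.1 ± 13.9 and 69.5 ± 31.5 FPKM. Collagen Col1a1 was at 8.4 ± 4.73 and 24.4 ± 19.3 FPKM, with 46.5 FPKM in KO-2 against 10.8 and 16 in KO-1 and KO-3. That list did not pass without WT-2 (0.405) or KO-2 (0.658).

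Hepatocyte transcripts did not move together. Albumin, Alb (chromosome 5, 90460897 to 90476602), the most abundant transcript in every library, was at 77684 ± 3162 and 30008 ± 5162 FPKM (log2 -1.39, adjusted p = 0.0559). It held 12.2%, 11.9% and 12.1% of the FPKM total in the wild-type libraries and 4.55%, 4.48% and 6.1% in the knockout libraries. Alb passed the test at adjusted p of 0.0324 after median-of-ratios scaling, 0.0218 with a mean of at least 2 FPKM required, 0.0186 with robust moderation and 0.00919 with no variance trend, and it did not pass with any 1 library left out (0.0623 to 0.219). Quantile normalization set its difference to 0, because the most abundant gene of every library is then given the same value. Of 20 hepatocyte markers 0 passed limma, 1 was lower adjusted over the list alone, and 1 was higher and 4 were lower at unadjusted p under 0.05. The median was -0.12 (camera adjusted p = 0.191, range over alternatives 0.0276 to 0.70, 0.0276 without KO-1). Transferrin, Trf, was at 10858 ± 413 and 9784 ± 788 FPKM and the transcription factor Hnf4a at 150.1 ± 9.21 and 123 ± 25.4 FPKM.

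Lists of enzymes and zonal genes of hepatocytes were then examined. Of 19 cytochrome P450 genes 1 rose, Cyp2f2, 2 were higher adjusted over the list alone, and the median was 0.01 (camera adjusted p = 0.155, range over alternatives 0.00869 to 0.866, 0.0236 without WT-2 and 0.00869 without KO-2). Cyp2e1 was at 2809 ± 489 and 2708 ± 783 FPKM. Of 21 genes of bile acid synthesis and transport 2 fell and 0 rose, against 4 lower and 3 higher adjusted over the list alone. Cyp7b1, of the alternative bile acid pathway, fell from 71 ± 24.2 to 26.9 ± 2.13 FPKM (adjusted p = 0.0356) and the sterol exporter Abcg8 from 53.9 ± 16.4 to 22.6 ± 1.93 FPKM (adjusted p = 0.0469). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 33.7 ± 13.2 and 37.2 ± 14.4 FPKM, with a sign that turned without WT-2 (-0.11) and KO-1 (-0.13). That list's median was 0.08, its mean -0.09 and its camera direction down (adjusted p = 0.362). Periportal genes (13 tested) held 2 rises, Cyp2f2 and Mup20, with 3 higher and 5 lower adjusted over the list alone. Their median was -0.16 and their mean 0.15, with camera downwards (adjusted p = 0.523) and fry upwards (adjusted p = 0.641). Pericentral and Wnt target genes (16 tested, 0 passed limma over all genes or over the list alone, 1 lower at unadjusted p under 0.05) had a median of -0.12 (camera adjusted p = 0.25, range over alternatives 0.0114 to 0.897), with Glul at 316 ± 47.9 and 264 ± 56.2 FPKM, and were called lower without KO-1 (0.0114) and turned upwards without KO-2 (0.897). Of 18 urea cycle and amino acid breakdown genes 0 passed limma, 2 were lower adjusted over the list alone and 1 was higher and 6 were lower at unadjusted p under 0.05, with a median of -0.26 (camera adjusted p = 0.00453, range over alternatives 0.000193 to 0.70, adjusted p = 0.70 with an estimated correlation, 0.209 by camera without KO-2). Hpd was at 1526 ± 112 and 1441 ± 452 FPKM and arginase Arg1 at 1044 ± 49.2 and 966 ± 216 FPKM.

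The RNA of genes of the pathway that Traf3 restrains showed no call. NIK protein was not measured, so these values do not show whether the pathway was active. Map3k14 (chromosome 11, 103219762 to 103267472), which encodes the kinase NIK, was at 1.2 ± 0.215 and 2.44 ± 0.397 FPKM (log2 0.64, limma adjusted p = 0.0698, range over its alternatives 0.0526 to 0.183). Its values were 0.949, 1.31 and 1.33 FPKM in the wild-type libraries and 2.01, 2.52 and 2.79 FPKM in the knockout libraries, without overlap. Nfkb2 was at 3.53 ± 0.344 and 4.63 ± 2.2 FPKM and Relb at 1.4 ± 0.454 and 1.68 ± 1.11 FPKM, and both signs turned without KO-2 (-0.05 and -0.22), that of Relb also without WT-2 (-0.04). Of 10 noncanonical NF-kB components 0 passed limma, with 1 higher and 1 lower both adjusted over the list alone and at unadjusted p under 0.05, Ltbr at 51.5 ± 0.701 and 43.9 ± 4.15 FPKM and Chuk at 39 ± 3.45 and 38.4 ± 0.894 FPKM. Their median was 0.11 (camera adjusted p = 0.679, range over alternatives 0.355 to 0.931), and the direction turned downwards without KO-2 (0.658), with no filter on low values (0.854) and with a mean of at least 2 FPKM required (0.719). NF-kB target genes (20 tested, 0 passed limma, 1 lower adjusted over the list alone, 6 lower at unadjusted p under 0.05) were lower as a list, with a median of -0.14 (camera adjusted p = 0.0223, range over alternatives 0.000485 to 0.563, adjusted p = 0.563 with an estimated correlation). Nfkbia was at 55 ± 8.84 and 35 ± 8.99 FPKM (adjusted p = 0.155) and Bcl3 at 15 ± 0.947 and 13 ± 4.04 FPKM, and the list did not pass without WT-3 (0.0908) or KO-3 (0.298).

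Inflammatory lists gave few calls. Of 20 acute phase genes 1 fell, Saa3, and adjusted over the list alone 8 were lower and 1 higher. The median was -0.13 (camera adjusted p = 0.0321, range over alternatives 0.0102 to 0.466, adjusted p = 0.466 with an estimated correlation), and the list did not pass without WT-1 (0.0894), WT-3 (0.132), KO-2 (0.0773) or KO-3 (0.0813). Of 19 interferon response genes 0 passed limma over all genes or over the list alone and 4 were higher at unadjusted p under 0.05, with Bst2 at 359.7 ± 28.4 and 331 ± 93.7 FPKM, Irf7 at 61.3 ± 11.2 and 48.6 ± 7.48 FPKM and a median of 0.05 (camera adjusted p = 0.367, range over alternatives 0.0134 to 0.968). That list was called higher without KO-3 (0.0134) and turned downwards without WT-2 (0.968) or KO-1 (0.794).

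Cell cycle genes were higher as a list at low values. All 24 tested members had higher means, 0 passed limma over all genes, 1 was higher adjusted over the list alone and 6 were higher at unadjusted p under 0.05. In 4 of the 24 all knockout values lay above all wild-type values, and 21.9% of all tested genes had no overlap in either direction. Mki67 was at 0.548 ± 0.443 and 1.39 ± 1.04 FPKM, with 2.57 FPKM in KO-2. KO-1 (0.611) and KO-3 (0.991) lay below WT-1 (1.06). Ccnd1, cyclin D1, was at 18.9 ± 8.31 and 26.8 ± 3.15 FPKM and Pcna at 24.7 ± 5.12 and 25.1 ± 2.82 FPKM. The median was 0.47 (camera adjusted p = 6.74e-06, adjusted p = 0.536 with an estimated correlation). Of 11 p53 targets and growth arrest genes 1 rose, Ccng1, cyclin G1, from 9.53 ± 0.25 to 16.4 ± 2.16 FPKM (adjusted p = 0.0387), and adjusted over the list alone 6 were higher and 1 lower. Cdkn1a, the cell cycle inhibitor p21, was at 1.22 ± 0.184 and 8.12 ± 5.48 FPKM (adjusted p = 0.0884, 0.0122 without KO-1, range over alternatives 0.0122 to 0.245). The p53 list had a median of 0.31 (camera adjusted p = 0.00147, adjusted p = 0.19 with an estimated correlation, fry adjusted p = 0.0208). Among 16 biliary and progenitor markers Fxyd3 rose from 1.05 ± 0.495 to 2.94 ± 0.245 FPKM (adjusted p = 0.0441) and 4 were higher adjusted over the list alone. Osteopontin, Spp1, was at 33.2 ± 2.98 and 129 ± 109 FPKM (39.4, 250.4 and 98.2 FPKM in KO-1, KO-2 and KO-3, adjusted p = 0.207, 0.0483 without KO-1, range over alternatives 0.0483 to 0.45). Epcam was at 0.675 ± 0.337 and 2.54 ± 1.4 FPKM, Sox9 at 0.387 ± 0.0671 and 1.06 ± 0.643 FPKM, Krt7 at 0.443 ± 0.189 and 0.806 ± 0.295 FPKM and Krt19 at 1.22 ± 0.771 and 1.56 ± 0.555 FPKM. The biliary list had a median of 0.34 (camera adjusted p = 0.00205, range over alternatives 2.1e-06 to 0.536, adjusted p = 0.536 with an estimated correlation) and did not pass without KO-2 (0.0773) or with a mean of at least 2 FPKM required (0.327).

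Of the stress and tumour lists, the unfolded protein and oncofetal lists each held 1 call. Of 17 NRF2 and glutathione genes 0 passed limma, 6 were higher and 1 lower adjusted over the list alone, and 7 were higher and 1 was lower at unadjusted p under 0.05, with a median of 0.59 (camera adjusted p = 0.00356, adjusted p = 0.466 with an estimated correlation). Gstm1 was at 755 ± 79.7 and 1101 ± 186 FPKM and catalase, Cat, at 1202 ± 114 and 1385 ± 145 FPKM. Of 14 genes of the unfolded protein and stress response 1 fell, asparagine synthetase Asns, from 2.15 ± 0.049 to 0.869 ± 0.144 FPKM (adjusted p = 0.0305), against 4 higher and 2 lower adjusted over the list alone. The chaperone Hspa5 was at 163 ± 8.15 and 436 ± 206 FPKM (adjusted p = 0.0716, 0.0416 without KO-2 and 0.0426 after quantile normalization, range over alternatives 0.0342 to 0.215). Creld2 was at 14.7 ± 1.45 and 54.4 ± 34.1 FPKM (adjusted p = 0.0742, 0.0368 without KO-2, range over alternatives 0.0368 to 0.218), and with the 10 most abundant genes left out both passed (0.0342 and 0.0484). That list had a median of 0.34 (camera adjusted p = 0.155, range over alternatives 0.0123 to 0.70, 0.0123 without KO-2). Of 8 oncofetal and liver tumour genes Akr1b7, an aldo-keto reductase, fell from 1.63 ± 0.195 to 0.367 ± 0.0382 FPKM (adjusted p = 0.015), with 1 higher and 2 lower adjusted over the list alone. The median was 0.02 and the mean 0.09, with camera downwards (adjusted p = 0.343). Of Fxyd3, Ccng1, Asns and Akr1b7, 1 passed without WT-1, 1 without WT-2, 0 without WT-3, 1 without KO-1, 1 without KO-2 and 2 without KO-3. Fxyd3 did not pass with an added constant of 0.1 nor Ccng1 with the 10 most abundant genes left out. With the replicate number as a block Fxyd3, Ccng1 and Asns did not pass. Notch pathway genes (9 tested, 0 passed limma, 1 higher adjusted over the list alone, 2 higher at unadjusted p under 0.05) had a median of 0.09 (camera adjusted p = 0.414), with Hes1 at 4.68 ± 0.378 and 10.3 ± 3.27 FPKM (adjusted p = 0.0726, 0.011 without KO-3, range over alternatives 0.011 to 0.219) and Notch2 at 4.77 ± 0.88 and 5.12 ± 0.883 FPKM. YAP and TEAD targets (12 tested, 0 passed limma over all genes, over the list alone or at unadjusted p under 0.05) had a median of -0.02 (camera adjusted p = 0.679, range over alternatives 0.451 to 0.906), with Wwc1 at 16.5 ± 2.17 and 19.7 ± 2.28 FPKM and Amotl2 at 8.42 ± 1.03 and 9.28 ± 0.959 FPKM, and turned upwards without WT-3 (0.692) or KO-1 (0.906).

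Lists of sex-biased genes and of handling were examined as checks. Of 11 male-biased liver genes Mup20 and the elongase Elovl3 rose, Elovl3 from 0.707 ± 0.364 to 3.66 ± 0.546 FPKM (adjusted p = 0.0129), and Cyp7b1 fell, against 3 higher and 1 lower adjusted over the list alone. The median was 0.83 (camera adjusted p = 0.00376, adjusted p = 0.49 with an estimated correlation). Of 14 female-biased genes Acot3 rose and Cyp3a16 fell, against 2 higher and 3 lower adjusted over the list alone. The median was 0.02 and the mean 0.07, with camera downwards (adjusted p = 0.764, range over alternatives 0.56 to 0.994) and upwards without WT-1 (0.763). Of Cyp7b1, Abcg8 and Elovl3, 3 passed without WT-1, 0 without WT-2 and 1 without each of the other libraries. Abcg8 did not pass without a variance trend, and neither Cyp7b1 nor Abcg8 passed with the replicate number as a block. Xist, the transcript of the inactive X chromosome, was at 44.6 ± 8.62 and 47.5 ± 5.71 FPKM, and its sign turned without WT-3 (-0.06). It lay between 34.9 FPKM (WT-3) and 53.9 FPKM (KO-2), so every library held RNA of female cells. No Y-linked gene of the list was in any library. A gene absent from WT-3 is in no list, so Y-linked genes in the knockout livers could not have been seen. Immediate early genes (11 tested, 0 passed limma, 2 higher adjusted over the list alone, 3 higher at unadjusted p under 0.05) had a median of 0.06 (camera adjusted p = 0.414), with Dusp1 at 30.3 ± 8.05 and 45.9 ± 10.7 FPKM and Zfp36 at 93.9 ± 6.45 and 87.6 ± 7.62 FPKM. Of the genes of pancreas, fat and mesothelium 1 could be tested, Cela1, at 32.2 ± 2.49 and 21.7 ± 13.9 FPKM, and of the mitochondrially encoded genes 0 were listed.

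**Figure D3:**
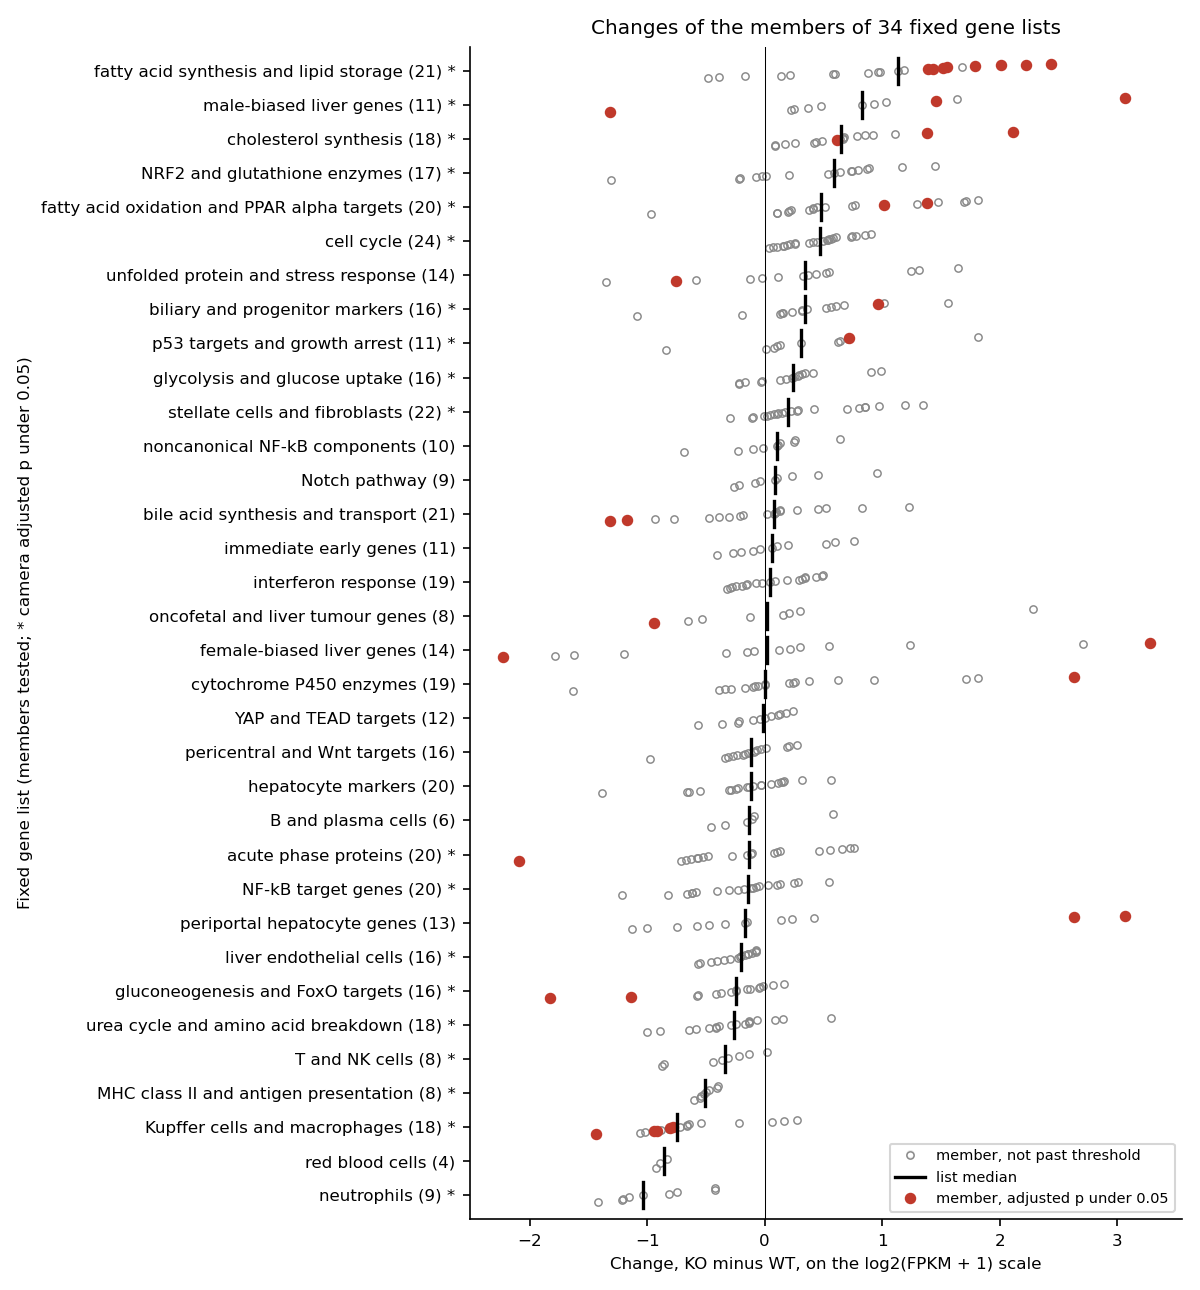
Log2 change of each tested member (points) of the 34 gene lists, on the log2(FPKM + 1) scale, with the median of each list as a black bar. Red points passed an adjusted p of 0.05 over all genes, an asterisk marks a list with a camera adjusted p under 0.05, and the number of members tested stands in brackets.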

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

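The alternative without the 10 most abundant genes was chosen after seeing the data, and all others before. The count of 164 genes was most affected by leaving out a library (19 to 217, with 18 of the 19 left without WT-2 among the 164), which leaves fewer samples. It was 92 with a log2 change of at least 1 also required. Other settings gave 133 (missing genes set to 0) to 225 (without the 10 most abundant genes). Of 66 called genes named, 54 to 66 kept their call under the settings that use all libraries and gene values and 13 to 49 with a library left out. Of these genes 0 turned direction. With a library left out none could turn, since called genes had no overlap between groups. The 19 lists became 0 with an estimated correlation and 4 with fry, and numbered 15 to 20 with a library left out. Pten lay between -0.58 and -0.48 (adjusted p 0.0594 to 0.259) and Traf3 between -0.51 and -0.24 (adjusted p 0.257 to 0.596, with no value at a mean of at least 2 FPKM). The gap between within-group and between-group correlations was 0.0094, and 0.0324 over the 2000 most abundant genes (the cause was not tested). Another scaling moved the median of all genes by -0.0152 to 0.00477.

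With the replicate number as a block, 186 genes passed, 122 of them among the 164, and 18 lists, the stellate list being lost (0.0634). Fasn then passed (adjusted p = 0.0306, range over its alternatives 0.0306 to 0.313) and of the cholesterol genes 1 rose in place of 3, of the fatty acid oxidation genes 5 in place of 2. Of the 12 largest falls 7 passed, without Igfbp2, Ptgds, Igfbp1, Lifr and Gbp2b. Of Fxyd3, Ccng1, Asns and Akr1b7 only Akr1b7 passed, and of Cyp7b1, Abcg8 and Elovl3 only Elovl3. Deviations from the group mean of same-numbered libraries correlated at 0.387, -0.107 and 0.194. The value for WT-1 and KO-1 was the highest of all pairs across the groups, while WT-2 correlated best with KO-3 (0.221). The numbers as a set therefore do not clearly pair the libraries. WT-1 and KO-1 also lay together on the second principal component (17.1 and 20.6), and whether they share a batch was not tested.

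Uncalled genes whose sign turned had these ranges of log2 change with a library left out: Srebf1 -0.44 to 0.079, Cyp7a1 -0.13 to 0.46, Nfkb2 -0.053 to 0.44, Relb -0.22 to 0.30, Xist -0.063 to 0.21, Arg1 -0.29 to 0.036, Bst2 -0.37 to 0.032, Chuk -0.062 to 0.052, Cyp2e1 -0.24 to 0.18, Dcn -0.19 to 0.13, Fcgr2b -0.33 to 0.043, Hpd -0.34 to 0.13, Notch2 -0.034 to 0.19, Pcna -0.056 to 0.19 and Sparc -0.12 to 0.47. Quantile normalization also turned Cyp2e1 (0.018) and Pcna (-0.0094). The cause was not tested. No count-based test was run because the values are FPKM, and no symbol was listed more than once. Depth limits low genes most, and since every list lies within that of WT-3, any gene seen in knockout livers alone is hidden.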

Other observations

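Tests of albumin share, feeding state, both cell share tests, blood content and hepatocyte loss, and the genes named in the next paragraph, were chosen after the result was seen.

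Outside the fixed lists, several metabolic and signalling genes were called. The retinaldehyde dehydrogenase Aldh1a1 rose from 203 ± 66 to 788 ± 165 FPKM (n = 3 per group, limma adjusted p = 0.0137), the intestinal fatty acid binding protein Fabp2 from 25.4 ± 1.71 to 114 ± 60.8 FPKM (adjusted p = 0.0309), galectin Lgals1 from 10.8 ± 1.23 to 44.2 ± 14.4 FPKM (adjusted p = 0.0129), the acetyl-CoA synthetase Acss2 from 32.4 ± 2.17 to 108 ± 45.4 FPKM (adjusted p = 0.0287) and monoglyceride lipase Mgll from 33.6 ± 0.916 to 74.6 ± 2.68 FPKM (adjusted p = 0.00475). The secretory pathway genes Sec24d, Sec22b, Ostc and Uso1 rose, with adjusted p between 0.0258 and 0.0456. The HDL receptor Scarb1 fell from 96.4 ± 7.65 to 48.1 ± 7.39 FPKM (adjusted p = 0.0207), the leptin receptor Lepr from 1.93 ± 0.143 to 0.532 ± 0.279 FPKM (adjusted p = 0.0314) and the vasopressin receptor Avpr1a from 10.4 ± 0.184 to 3.31 ± 0.563 FPKM (adjusted p = 0.00475). The costimulatory ligand Icosl fell from 4.3 ± 0.576 to 0.814 ± 0.23 FPKM and the BMP antagonist Grem2 from 4.98 ± 0.356 to 1.03 ± 0.348 FPKM (adjusted p = 0.00475 for both). Cbs, an enzyme of cysteine synthesis, fell from 336 ± 42.9 to 156 ± 38.9 FPKM (adjusted p = 0.0387) and the secreted protein Itih3 from 565 ± 36 to 283 ± 59 FPKM (adjusted p = 0.0419). Of these 16 genes 8 passed without WT-1, 4 without WT-2, 6 without WT-3, 7 without KO-1, 9 without KO-2 and 14 without KO-3. Their direction could not turn in these cases, since their groups do not overlap. Uso1 did not pass without a variance trend.

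Among genes not listed in every library, 187 were listed in all wild-type libraries and no knockout library. Given the nesting, a filter at 0.1 FPKM would require only KO-3 to lie under it for them. That filter is inferred, no knockout value is given for these genes, and the cause of their absence was not tested. Ndufs5, a subunit of respiratory complex I, was at 11.2, 12.8 and 10.7 FPKM in the wild-type libraries and Scgb1a1 at 19, 6.57 and 3.58 FPKM. The complement gene C1s2 was at 0.102, 14.2 and 14.2 FPKM and C1rb at 0.171, 6.45 and 6.92 FPKM in WT-1, WT-2 and WT-3. Sult2a6 (13.5 and 14.2 FPKM) and H2-Q6 (6.07 and 11.5 FPKM) were listed in WT-2 and WT-3 and not in WT-1. WT-1 thus differed from the other wild-type libraries in these genes, and the cause was not tested.

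The real split gave 164 genes and the highest of the other 9 splits into 3 and 3 gave 0, so 1 of 10 splits reached the real count. For lists the real split gave 19 and the highest other 18, again 1 of 10. The 10 splits are too few for a share under 0.05.

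Lipid synthesis genes were higher in the knockout livers with camera's preset correlation, but with an estimated correlation neither the fatty acid nor the cholesterol list passed (adjusted p = 0.19 for both), and the cholesterol list did not pass fry (0.0525). A smaller albumin share would raise every other gene, but only slightly, since Alb held 11.9% to 12.2% of the wild-type FPKM total. The median change of all tested genes was 0.00342, so no general rise was seen. The bound set for this test lay above any rise that share could give, so its outcome was fixed in advance. A difference in feeding should move fatty acid oxidation genes the opposite way, and their mean difference was 0.697 (95% interval 0.243 to 1.15, above 0 with each library left out in turn). However, gluconeogenesis and FoxO targets were lower, as feeding would make them (14 of 16 by log2 change, camera adjusted p = 0.00166, 0.466 with an estimated correlation). Feeding therefore stays open. The clock score differed by -0.222 (95% interval -0.531 to 0.0879), inside the bound of 1 set beforehand, but its members went both ways (Ciart 4.37 ± 0.859 and 16.7 ± 14 FPKM, Per2 4.74 ± 0.822 and 8.56 ± 2.21 FPKM, Nr1d1 48.1 ± 2.46 and 36.1 ± 13 FPKM), so its mean decides little and the time of collection stays open. That targeting of Pten may raise these genes is a hypothesis that livers with only Pten or only Traf3 targeted would test, and no such group was analysed here. For these genes and the macrophage and Alb patterns below, an effect of Cre or tamoxifen also stays open. It could not be tested, since no group carried Cre without floxed alleles.

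Macrophage markers (18 tested, 5 called and 15 with lower means, 0 of them in another list) were lower as a list with camera's preset correlation and fry, but not with an estimated correlation (adjusted p = 0.19). A lower share of all non-hepatocyte cells should lower stellate markers alike. The macrophage minus stellate difference was -1.01 (95% interval -1.89 to -0.134). It rests on all libraries together, since the interval included 0 without WT-1, WT-2, WT-3 or KO-3 (upper bounds 0.211, 0.32, 0.229 and 0.286) and KO-2 stood apart in collagen. The stellate score alone changed by 0.367 (95% interval -0.536 to 1.27). By camera's preset the stellate list was higher, while the endothelial, neutrophil and T and NK cell lists were lower. Marker RNA also does not separate cell share from expression per cell, so a lower share of non-hepatocyte cells stays open. A shared loss of macrophages and endothelium stays open, with a difference of -0.393 (95% interval -1.2 to 0.414). Less blood in the tissue also stays open. Resident Kupffer markers (Clec4f, Timd4, Vsig4, Marco, Cd5l), which do not circulate, changed by -1.05 (95% interval -1.86 to -0.243), but 3 of the 5 are among the called falls. The medians of red blood cell (-0.86) and neutrophil genes (-1.03) went with less blood, though the red blood cell list turned upwards without WT-1 or KO-3. Fewer macrophages, or lower expression in each, may both underlie the lower macrophage markers and were not separated.

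Alb and Serpina1e had lower means in the knockout livers, Alb without passing the test. A general fall of hepatocyte transcripts relative to the rest of the library is argued against by the other 19 members of the hepatocyte marker list. Their median was -0.101 (interquartile range 0.392), and 0 were lower than Alb. FPKM is scaled to each library, so an even loss of hepatocyte RNA would be scaled away and could not be seen. Genes linked to the engineered loci stay open, since 3.16% of 158 called genes against 2.48% of 11383 tested lay within 10 Mb of Pten, Traf3 or Alb, with these 3 genes and Serpina1e left out of the count (one-sided Fisher's exact p = 0.354). The called genes counted were Cyp2c39, Cyp2c67, Cyp2c70 and Hhex near Pten (4 of 113 tested) and Uso1 near Alb (1 of 70). Near Traf3 0 of 99 were called. Serpina1e itself, left out of these counts and also called, lies 7.22 Mb from Traf3. Its near-identical copies were at 1460.1 ± 149 and 883 ± 249.6 FPKM (Serpina1a), 3545 ± 222 and 3061 ± 526 FPKM (Serpina1b), 2593 ± 199.5 and 2161 ± 746 FPKM (Serpina1c) and 2517 ± 236 and 2067 ± 382 FPKM (Serpina1d), so a strain variant or shared reads could contribute and were not tested.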
